A study of Mus musculus with 6 samples.

How the data were processed

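The samples were 6 RNA-seq libraries of cultured mouse podocyte cells, 3 of a Myosin 1e knockout line and 3 of a WT podocyte line. Per the labels' protocols, RNA was taken with an RNeasy kit and 100 ng of total RNA went into stranded mRNA libraries from an Illumina kit. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.3a, featureCounts, Subread 1.6.4 and edgeR, and the genome build was GRCm38. The gene annotation, the strand setting of the counting, the filter and the prior count are not given in the sources used here. Reads of genes that overlap on opposite strands therefore could not be assigned with certainty.

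The authors deposited 1 table of log2 CPM (counts-per-million) with a column for each library. The deposited log2 values share a lowest value of -5.26 in all columns. After subtracting that value on the linear scale, 100% of values were whole multiples of the smallest step of their column, within a tolerance of 0.001. Whole reads, the prior (1 read on average) and the scaling factor of each library followed from these steps. The factors were 0.983, 0.989 and 1.02 for KO libraries 1 to 3 and 1.01, 1.01 and 0.989 for WT libraries 1 to 3, with a geometric mean of 1. The library size used for scaling is thus the total of the listed genes, and reads that fell outside the listed genes are not in it. The library with the second-highest level had at least 1.01 CPM in every gene and the third-highest could be as low as 0.324 CPM, as a filter on 2 libraries gives. Genes low in all libraries were therefore not analysed here. CPM values in the text are the recovered reads on the scale of that library size, without the prior.

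Depth was 35447096 to 42106461 reads in the listed genes. Where a gene had 0 reads in a group, folds were bounded against 3 reads over the group. Where it had 1 to 3, the ratio is given with an exact 95% interval from the binomial (Clopper-Pearson) distribution of the reads. These intervals do not cover variation between cultures or amplification. Fitted log2 fold changes of genes near 0 reads depend on the prior, so levels and ratios are given for them.

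Symbols were matched to GENCODE M21, an annotation of GRCm38 that need not be the one the authors used. Of the listed genes, 12673 symbols were found in it and 12655 had 1 position. Coordinates count from 1.

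The main test was limma (version 3.58.1, R 4.3.3) on the deposited log2 CPM, with lmFit and with eBayes using an intensity trend, KO minus WT, without covariates. The 12616 genes with more than 0 log2 CPM in at least 3 of the 6 libraries were tested and 187 were not. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The test for Myo1e was also made as an exact permutation test. The unit of the table is log2, so count models were not the main test, and limma voom on the recovered reads was an alternative. On simulated reads for this comparison with a dispersion of 0.01, 200 of 12082 tested genes were changed. The procedure called 100% of the 100 genes changed 2-fold and 100% of the 100 changed 4-fold, and 14 of the 11882 unchanged genes. These rates hold for that setting only, with means taken from the WT libraries and 1 dispersion for all genes. In the real data far more genes passed and some had a larger spread, so the rates need not carry over.

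Gene lists were tested with camera, with its preset correlation of 0.01 between genes and also with an estimated correlation, and with fry, each adjusted over the 31 lists. With an estimated correlation, camera has only the few degrees of freedom that 6 libraries leave, so its p-values can be larger for that reason alone. fry asks whether the genes of a list move on balance to one side, without comparing them with other genes. A list needed at least 3 tested members. The lists were fixed from textbook knowledge before the data were examined. They covered class I myosins, other myosin heavy chains, podocyte identity, nephrotic syndrome genes, clathrin-mediated endocytosis, actin assembly, focal adhesion, contractile genes, fibrillar matrix, basement membrane, cell-cell junctions and mesenchymal transcription factors. Markers of parietal and tubular epithelium, mesangial cells with pericytes and fibroblasts, endothelium and leukocytes stood for other cell types. The others covered the cell cycle, p53 targets, the interferon response, MHC class I, inflammatory genes, YAP/TEAD targets, the TGF-beta pathway, glycolysis and hypoxia, cholesterol and lipid synthesis, and heat and cold shock. Sex-linked, housekeeping, mitochondrially encoded and strain-variable genes completed them.

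The rule for named genes was also fixed then. It takes all tested class I myosins and the 12 genes that rose most and the 12 that fell most among those past the threshold. These had to have groups that did not overlap, a mean of at least 5 log2 CPM in the higher line and a gene symbol of the named kind. From each list it takes up to 3 risen and 3 fallen members with the largest change. Podxl, Synpo, Wt1, Cd2ap, Tjp1, Actn4, Dnm2 and Synj1 were always included, as was Nphs1 where tested. Not every gene that the rule takes is described here.

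Alternatives chosen before the data were examined were median-centred libraries, quantile normalization, 1 CPM added before the logarithm, no filter, and a stricter filter of 2 log2 CPM. The variance model was run without the trend and with a robust trend, and with sample weights. A block for the replicate number, each library left out in turn (6 fits), voom, and limma treat against 2-fold were also run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps. Shifts of chromosomes were tested with 10000 random draws of as many genes, adjusted over 20 chromosomes. That step was tested on shuffled values with 1 chromosome shifted, which it called. Variation along a chromosome was tested with 10000 random gene orders within it, on the range of the medians of its 3 parts.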

Results

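Messenger RNA was sequenced in 6 libraries of mouse kidney podocyte cells, the epithelial cells that wrap the glomerular capillaries and hold the slit diaphragm of the kidney filter. The WT group held 3 libraries of the WT podocyte line that the labels call Mundel. The KO group held 3 libraries of a podocyte-derived line that the labels call a Myosin 1e knockout. The design text also names a heterozygous genotype, which was not analysed here. The table listed 12803 genes as log2 CPM (counts-per-million), from which the whole reads of each library were worked back. The listed genes held 41360689, 35447096 and 37045463 reads in the KO libraries and 42106461, 38314734 and 35763961 reads in the WT libraries. At these depths 3 reads equal between 0.0703 and 0.0856 CPM. The 10 most abundant genes of a library took 4.74% to 5.50% of its reads in the KO group and 3.36% to 3.47% in the WT group. Each genotype was represented by 1 cell line, so every difference given here is a difference between those lines and cannot be divided between the genotype and other differences of the lines. The labels call the replicates biological without saying how the cultures were kept apart, so the p-values measure the spread between these samples. Levels are means ± SD of the 3 libraries of a group, in CPM.

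The series concerns mutations of MYO1E, a gene of steroid-resistant nephrotic syndrome, and the comparison of the lines asks how podocyte cells labelled as lacking this motor differ in their transcripts from WT podocytes. Myo1e encodes a long-tailed class I myosin, an actin-based motor that binds membranes. It lies on chromosome 9 from 70207350 to 70399766 on the plus strand (GRCm38, ENSMUSG00000032220, protein-coding). Its level was 18.9, 16.3 and 16.8 CPM in the KO libraries and 184, 180 and 168 CPM in the WT libraries, so the labels and the targeted gene went the same way in all 6. The mean was 17.3 ± 1.4 CPM in the KO line and 177 ± 8.4 CPM in the WT line. The log2 fold change was -3.35 with an SE of 0.09 (limma, adjusted p = 2.1e-08). An exact two-sided permutation test of the groups gave p = 0.1, the smallest value that 3 libraries against 3 allow. The KO line kept 9.79% of the WT level (exact 95% interval 9.34% to 10.2%, from 1973 reads in KO and 20757 in WT). This interval and the others below cover counting error only. The reads are given per gene, so it was not possible to say which part of the transcript they came from.

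Of the other class I myosins tested, Myo1d was higher in the KO line at 151 ± 12 against 57.4 ± 4.2 CPM (log2 fold change 1.40). Myo1c was at 477 ± 28 in the KO line and 470 ± 44 CPM in the WT line and did not pass the test (log2 fold change 0.03, adjusted p = 0.82). The 4 tested members of the list held 2 that rose and 1 that fell, and the list as a whole did not pass (camera adjusted p = 0.918). The median of its log2 fold changes was 0.26 and the mean -0.36, which differ in sign. Among 15 other myosin heavy chains, 9 rose and 3 fell, or 10 and 3 adjusted over the list alone. The nonmuscle myosin Myh14 was at 293 ± 52 CPM in the KO line and 0.295 ± 0.09 CPM in the WT line. The class V motor Myo5c was at 57.0 ± 3.7 against 0.0846 ± 0.033 CPM. Myo3b had 3 reads in the WT group and 5683 in the KO group, a ratio of 1950 with a counting interval of 667 to 9460. Its WT level went from 0.0267 to 0.0141 CPM without WT replicate 2. Myh10, Myo6 and Myo9a fell, the last from 292 ± 9.8 to 83.9 ± 13 CPM. This list did not pass (camera adjusted p = 0.0849), but did so without WT replicate 2 (adjusted p = 0.0437, with 0.0437 to 0.133 over 16 other camera fits with the preset correlation; adjusted p = 0.825 with an estimated correlation).

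**Figure D1:**
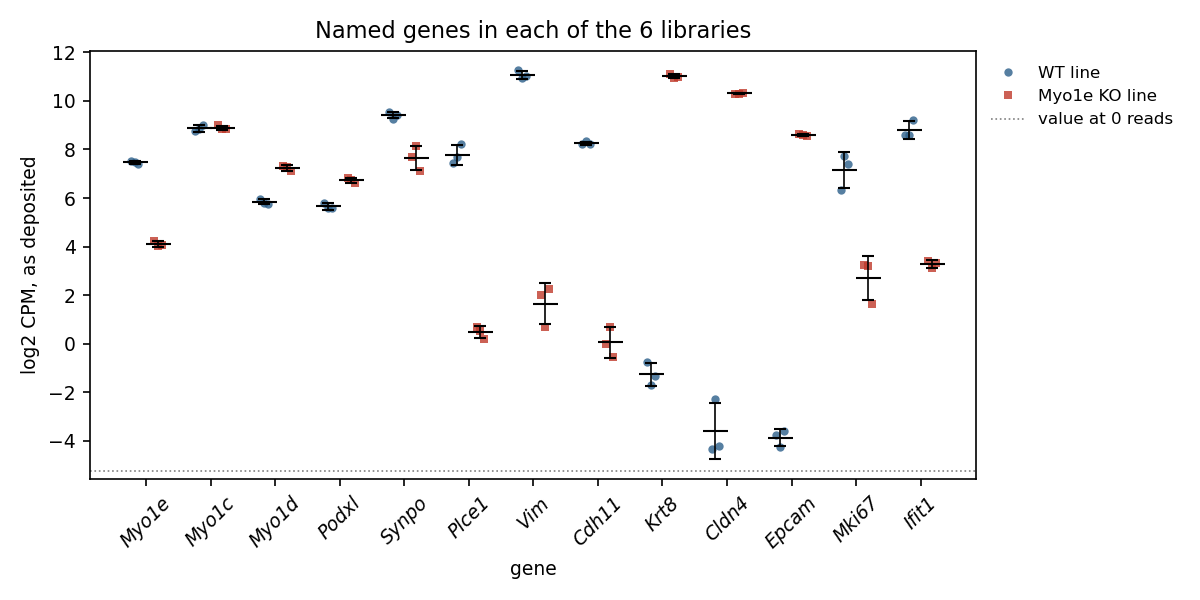
Deposited log2 CPM of 13 genes in each library, with WT libraries as circles, KO libraries as squares, and the mean with its SD in black (n = 3 each). Myo1e lay at 4.11 on average in the KO line and 7.47 in the WT line, and the dotted line marks the value of -5.26 that the table gives at 0 reads.

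Across the transcriptome the lines differed in most genes. Of 12616 genes tested, 8590 passed the threshold (68.1%), 4329 higher and 4261 lower in the KO line. A change of at least 2-fold was found in 3517 of them (27.9% of the genes tested), of which 1472 were higher and 2045 lower. At least 16-fold separated the lines in 445 higher and 473 lower genes on the fitted scale, which depends on the prior reads where a line is near 0. The groups did not overlap in 9278 genes (73.5%), against 10% expected by chance for 3 libraries against 3. Correlations of log2 CPM across genes were at least 0.988 within a group and 0.698 to 0.713 between groups, with genes not being independent replicates. The first principal component took 96.3% of the variance.

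The genes that rose most included keratins and claudins. Keratin 19 (Krt19, chromosome 11, 100140810 to 100148665) was at 805 ± 75 CPM in the KO line, with 2 reads in the whole WT group and a ratio of 47191 (counting interval 13063 to 389676). Krt18 was at 1070 ± 61 against 0.0509 ± 0.069 CPM, and the tight-junction gene Cldn4 (chromosome 5, 134945119 to 134946934) at 1271 ± 25 against 0.0776 ± 0.09 CPM. Epcam, an epithelial adhesion molecule, was at 386 ± 12 against 0.0431 ± 0.016 CPM, and the axonal adhesion gene Cntn2 at 414 ± 88 against 0.0633 ± 0.088 CPM. The desmosomal cadherin Dsg2 and the integrin activator Fermt1 were at 222 ± 36 and 317 ± 53 CPM, each with 1 read in the WT group. Their ratios were 25802 (4631 to 1.02e+06) and 37234 (6682 to 1.47e+06). Cldn3, Cldn7, Mal2, Wfdc2 and the epithelial splicing factor Esrp1 had 0 reads in all WT libraries. Against 3 reads over the group, Cldn3 was at least 12905-fold higher, Wfdc2 at least 11399-fold, Cldn7 at least 10335-fold, Mal2 at least 8329-fold and Esrp1 at least 5744-fold. Single libraries decided some of the low WT levels. Without WT replicate 2, Cldn4 and Krt18 were at 0.0258 and 0.0117 CPM in the WT line, and their log2 fold changes went from 13.91 to 14.58 and from 14.16 to 14.86. That of Cntn2 went from 12.65 to 13.44 without WT replicate 1, and its WT level was 0.0949 CPM without WT replicate 3.

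Among the genes that fell most, the membrane-bound collagenase Mmp14 fell from 139 ± 11 to 0.0442 ± 0.077 CPM, the chemokine Cxcl12 from 199 ± 35 to 0.062 ± 0.016, and Svep1 from 559 ± 145 to 0.219 ± 0.041 CPM. Scarf2, Eva1b, Aebp1 and the mineralisation inhibitor Mgp went from 206 ± 9, 117 ± 5, 217 ± 28 and 75.0 ± 20 CPM to 0.0442 ± 0.077, 0.0557 ± 0.057, 0.147 ± 0.088 and 0.0436 ± 0.056 CPM. The methyltransferase Inmt, among the most abundant of them, went from 1484 ± 129 to 1.16 ± 0.8 CPM. The antioxidant enzyme Prdx4 had 0 reads in the KO libraries and 54.7 ± 2.1 CPM in the WT libraries, at least 2069-fold lower. Zfp275, the cathepsin Ctsz and Ppp2r2b kept 1, 2 and 3 reads in the KO group. Their ratios of WT to KO were 6388 (1146 to 252352), 5236 (1449 to 43238) and 2609 (893 to 12656). The reads of Zfp275 and Ctsz were all in KO replicate 3, and the KO level of Ppp2r2b went from 0.0279 to 0.0133 CPM without KO replicate 2. All 5 KO reads of Mmp14 and all 5 of Scarf2 were in KO replicate 3. Without it their log2 fold changes went from -11.51 to -12.38 and from -12.08 to -12.94, where the KO level was 0 CPM and the prior set the size. Without the same library that of Mgp went from -10.35 to -10.97, and the KO level of Inmt was 0.735 CPM. The log2 fold change of Eva1b went from -10.79 to -10.12 without KO replicate 1 and its KO level to 0.0265 CPM without KO replicate 2, and the KO level of Aebp1 was 0.0969 CPM without KO replicate 1.

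**Figure D2:**
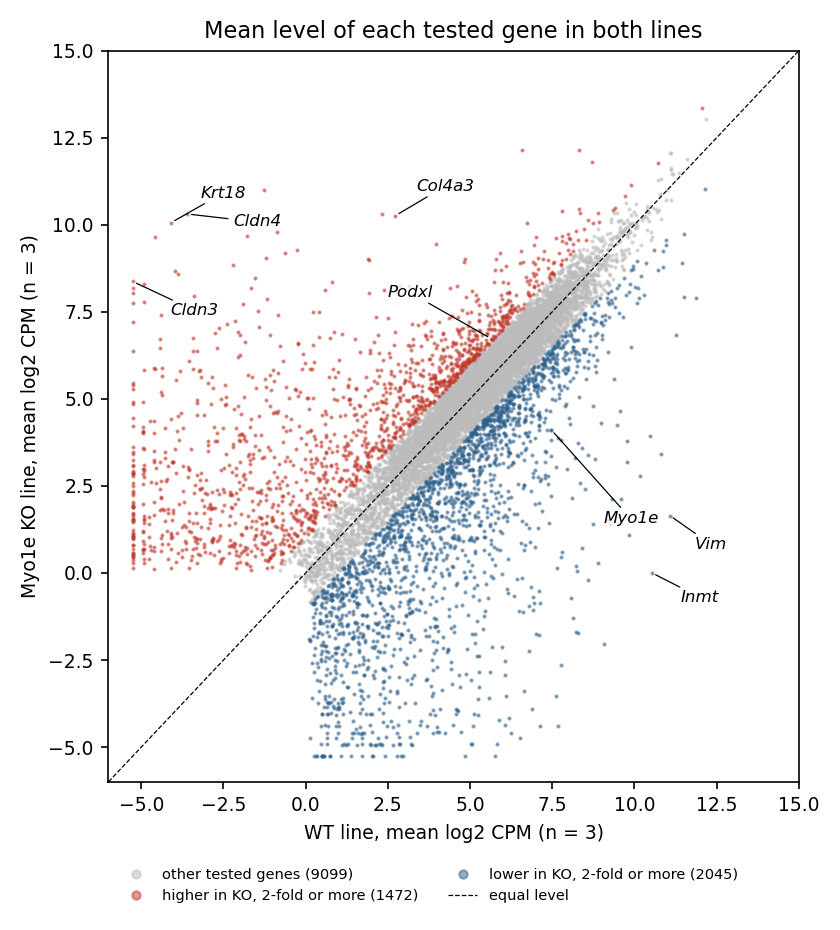
Mean log2 CPM of each of the 12616 tested genes in the WT line (horizontal axis) and in the Myo1e KO line (vertical axis), n = 3 libraries each. Genes past the threshold and 2-fold are red where higher in KO (1472) and blue where lower (2045), and the left and lower edges hold genes with 0 or few reads in one line.

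Most tested genes of cell-cell junctions rose in the KO line. Of 44 tested members 30 rose and 9 fell, with a median log2 fold change of 1.28 (camera adjusted p = 5.8e-05; adjusted p = 0.338 with an estimated correlation). Besides the claudins, the risen members held desmosomal and tight-junction genes. The members that fell furthest were the mesenchymal cadherin Cdh11, from 306 ± 13 to 1.07 ± 0.48 CPM, the nectin Nectin3, from 29.3 ± 4 to 0.915 ± 0.25 CPM, and the pore-forming claudin Cldn2, from 71.7 ± 4.5 to 4.51 ± 1.3 CPM. Tjp1, which encodes the scaffold ZO-1, was at 300 ± 33 against 239 ± 7.5 CPM (log2 fold change 0.32, adjusted p = 0.017). It did not pass without KO replicate 1 (adjusted p = 0.0621) or KO replicate 2 (adjusted p = 0.058), with 0.000899 to 0.0621 over the alternatives.

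Most of the tested markers of tubular epithelium rose. Of 35 markers 19 were tested and 16 were not, and of those tested 13 rose and 5 fell, with a median log2 fold change of 8.0, also with genes at 0 reads set to their bound (camera adjusted p = 0.0012; adjusted p = 0.338 with an estimated correlation). Those that rose included keratins and claudins of the distal nephron and collecting duct, which other simple epithelia also express. The proximal water channel Aqp1 fell from 640 ± 202 to 2.7 ± 0.77 CPM and the proximal endocytic receptor Lrp2 from 331 ± 121 to 14.1 ± 5.1 CPM. The kidney cadherin Cdh16 fell from 975 ± 209 to 92.5 ± 27 CPM. Of 15 parietal epithelial markers, 7 rose and 7 fell (camera adjusted p = 0.794, median log2 fold change -0.26 and mean 2.88). Krt8 rose to 2065 ± 119 from 0.405 ± 0.14 CPM, while the kidney transcription factor Pax2 fell from 352 ± 16 to 60.7 ± 3.6 CPM, Ncam1 from 164 ± 32 to 17.4 ± 2.5 CPM and Vcam1 from 134 ± 12 to 24.9 ± 8.8 CPM.

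All 12 tested mesenchymal transcription factors and markers fell, with a median log2 fold change of -3.65 (camera adjusted p = 3.5e-06; adjusted p = 0.338 with an estimated correlation). Vim, the intermediate filament vimentin (chromosome 2, 13573927 to 13582826), went from 2168 ± 257 to 3.44 ± 1.6 CPM, or 0.16% of the WT level. Tbx18 went from 90.3 ± 4.4 to 0.488 ± 0.27 CPM and the repressor of E-cadherin Zeb1 from 102 ± 0.47 to 1.71 ± 0.16 CPM. Among 43 genes of fibrillar matrix and its remodelling, 10 rose and 28 fell, or 11 and 28 adjusted over the list alone. Their median log2 fold change was -1.32 (camera adjusted p = 0.0012; adjusted p = 0.714 with an estimated correlation). Loxl2, a collagen crosslinking enzyme, fell from 59.2 ± 8.4 to 0.0341 ± 0.03 CPM, and Efemp2, a glycoprotein of elastic fibres, from 282 ± 23 to 0.392 ± 0.11 CPM. Its relative Efemp1 rose to 88.4 ± 6.9 from 0.039 ± 0.068 CPM, Fbln5 to 114 ± 31 from 12.7 ± 1.2 CPM and Vcan to 7.89 ± 3.3 from 1.47 ± 0.025 CPM. All 5 WT reads of Efemp1 were in WT replicate 1. Without that library its log2 fold change went from 10.91 to 11.72, where the WT level was 0 CPM and the prior set the size.

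Most of the tested podocyte identity genes fell in the KO line. Of 40 genes 29 were tested, of which 8 rose and 18 fell, or 8 and 19 adjusted over the list alone, with a median log2 fold change of -1.33 (camera adjusted p = 0.0157; adjusted p = 0.338 with an estimated correlation). The actin-associated gene Synpo was at 209 ± 71 against 681 ± 59 CPM (log2 fold change -1.76, SE 0.22, adjusted p = 0.00015). Podxl, the sialomucin of the podocyte surface, was at 106 ± 8.4 against 50.4 ± 4.7 CPM (log2 fold change 1.08, SE 0.10, adjusted p = 1.8e-05). Cd2ap, a slit-diaphragm adaptor, was at 390 ± 27 against 275 ± 38 CPM (log2 fold change 0.51, adjusted p = 0.0037). The transcription factor Wt1 was low in both lines, at 0.125 ± 0.1 in KO and 4.40 ± 2.0 CPM in WT, and passed the test (adjusted p = 5e-05). The phospholipase Plce1 fell from 226 ± 65 to 1.37 ± 0.24 CPM, Foxd1 from 38.5 ± 4.4 to 0.0784 ± 0.021 CPM and Sema3g from 44.4 ± 24 to 0.167 ± 0.022 CPM. Without WT replicate 3 the log2 fold change of Sema3g went from -7.65 to -8.24, and without KO replicate 3 the KO level of Wt1 was 0.0674 CPM. Tdrd5, Bmp7 and Clic5 rose, to 9.58 ± 1.7, 4.33 ± 1.5 and 3.11 ± 0.49 CPM. Nphs1, which encodes nephrin, was not among the genes of the table used here.

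Genes mutated in inherited nephrotic syndrome went both ways. Of 57 tested members, Myo1e included, 20 rose and 23 fell, and the list did not pass (median log2 fold change -0.03, camera adjusted p = 0.794). Col4a3 and Col4a4, the collagen IV chains of the mature glomerular basement membrane, were at 1252 ± 289 against 8.74 ± 8.3 CPM and at 707 ± 119 against 20.3 ± 19 CPM. Without WT replicate 1, their log2 fold changes went from 7.54 to 8.27 and from 5.47 to 6.18. The integrin Itgb4 was at 602 ± 171 against 0.643 ± 0.21 CPM. Besides Plce1 and Wt1, the formin Daam2 was among those that fell, from 10.4 ± 1.3 to 0.472 ± 0.11 CPM. The crosslinker Actn4 was at 1025 ± 76 in KO and 944 ± 82 CPM in WT and did not pass (log2 fold change 0.12, adjusted p = 0.36).

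Clathrin-mediated endocytosis and actin assembly, processes in which class I myosins take part, also had members on both sides. Of 49 endocytosis genes 19 rose and 16 fell (camera adjusted p = 0.877). The membrane-bending endophilin Sh3gl2 rose to 24.2 ± 1.1 from 0.503 ± 0.18 CPM and Epn3 to 91.7 ± 9.4 from 22.4 ± 6.8 CPM. The dynamin Dnm3 fell from 105 ± 16 to 12 ± 0.68 CPM and Hip1 from 125 ± 7.8 to 40.6 ± 0.95 CPM. Dnm2, the dynamin found in all tissues, was at 166 ± 6.7 against 139 ± 3.3 CPM (log2 fold change 0.26, adjusted p = 0.01). The phosphatase Synj1 was at 43.3 ± 2.1 against 51.8 ± 2.2 CPM (log2 fold change -0.26, adjusted p = 0.018), and did not pass without WT replicate 3 (adjusted p = 0.0537, with 0.0176 to 0.0537 over the alternatives). Of 57 actin assembly genes 28 rose and 16 fell (camera adjusted p = 0.315). Cyfip2, a subunit of the WAVE complex, rose to 280 ± 19 from 1.5 ± 0.26 CPM, and the bundling protein Pls3 to 606 ± 88 from 151 ± 7.1 CPM. The filopodial bundler Fscn1 fell from 642 ± 96 to 4.45 ± 1.3 CPM, the formin Fmnl3 from 388 ± 17 to 68.5 ± 8.8 CPM and Fhod1 from 101 ± 16 to 20.4 ± 2.1 CPM.

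Genes of matrix adhesion and of the basement membrane had members on both sides. Of 46 focal adhesion and integrin genes 15 rose and 21 fell (camera adjusted p = 0.822, median log2 fold change -0.17 and mean 0.41). The collagen-binding integrin Itga2 rose to 26.4 ± 3.8 from 0.197 ± 0.015 CPM, while Itga9 fell from 222 ± 26 to 1.71 ± 1.1 CPM and Itga1 from 244 ± 28 to 53.3 ± 5.5 CPM. The focal adhesion protein Tns2 fell from 175 ± 11 to 17.4 ± 1.1 CPM. Of 31 basement membrane genes 22 were tested, of which 9 rose and 8 fell (camera adjusted p = 0.978, median log2 fold change -0.11 and mean 0.64). Lamb3, a chain of the epithelial laminin, rose to 359 ± 50 from 0.357 ± 0.22 CPM. Frem2 had 1923 reads in the KO group and 1 in the WT group, a ratio of 1980 (355 to 78241). Col4a1 fell from 3755 ± 508 to 262 ± 119 CPM, Nid1 from 317 ± 54 to 0.313 ± 0.18 CPM and Nid2 from 1423 ± 104 to 15.6 ± 3.2 CPM. Of 28 contractile and smooth-muscle genes 8 rose and 9 fell (camera adjusted p = 0.822). Tagln fell from 1157 ± 135 to 7.14 ± 2.2 CPM, the myosin light chain Myl9 from 125 ± 13 to 14.8 ± 1.3 CPM and its kinase Mylk from 457 ± 53 to 56.1 ± 15 CPM. The tropomyosin Tpm2 rose to 84.9 ± 18 from 0.076 ± 0.051 CPM and Tpm1 to 4314 ± 341 from 2195 ± 132 CPM. The low level was 1.09 CPM for Itga9 without KO replicate 2, 0.231 CPM for Lamb3 without WT replicate 1 and 0.0493 CPM for Tpm2 without WT replicate 2.

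Proliferation genes were lower in the KO line. Of 55 cell cycle genes 50 fell and 2 rose, with a median log2 fold change of -2.09 (camera adjusted p = 4.4e-10; adjusted p = 0.714 with an estimated correlation). Mki67, a marker of cycling cells, was at 7.29 ± 3.6 against 153 ± 67 CPM, the mitotic kinesin Kif11 at 3.35 ± 1.6 against 74.4 ± 28 CPM and Ccnb2 at 1.03 ± 0.47 against 21.7 ± 8.1 CPM. The exceptions were the cyclins of the early cycle Ccnd1, at 755 ± 161 against 234 ± 102 CPM, and Ccnd2, at 1087 ± 136 against 625 ± 64 CPM. Of 40 p53 targets and cell-cycle inhibitors 17 rose and 15 fell (camera adjusted p = 0.918, median log2 fold change 0.02 and mean -0.15). Perp, Gdf15 and Pmaip1 rose, to 487 ± 56, 809 ± 204 and 389 ± 47 CPM from 98.7 ± 23, 261 ± 52 and 128 ± 16 CPM. The inhibitor Cdkn2c fell from 69.8 ± 9.3 to 0.703 ± 0.12 CPM, Cdkn1c from 7.93 ± 1.2 to 1.10 ± 0.2 CPM and Fas from 49.0 ± 8.7 to 8.79 ± 2.1 CPM.

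Interferon-response genes were lower in the KO line with no member higher. Of 53 tested members 46 fell and 7 did not pass, with a median log2 fold change of -2.28 (camera adjusted p = 1.1e-12; adjusted p = 0.592 with an estimated correlation). Ifit1, an RNA-binding antiviral protein, was at 9.78 ± 1.0 against 456 ± 120 CPM. Oas2 was at 0.121 ± 0.056 against 51.2 ± 19 CPM and Gbp5 at 1.03 ± 0.33 against 43.3 ± 4.8 CPM. Oas2 and Gbp5 belong to families with close copies, so reads could be shared between members. In 23 genes of MHC class I and antigen processing 16 fell and 1 rose, with a median log2 fold change of -0.78 (camera adjusted p = 0.0027; adjusted p = 0.706 with an estimated correlation). The immunoproteasome subunits Psmb10 and Psmb9 fell from 90.0 ± 8.4 to 15.2 ± 1.9 CPM and from 65.0 ± 4.9 to 19.2 ± 0.16 CPM. The chaperone Canx rose to 1062 ± 52 from 805 ± 28 CPM. Of 44 inflammatory genes 28 were tested, of which 9 rose and 12 fell (camera adjusted p = 0.822). Lcn2, an iron-binding protein released by stressed epithelium, rose to 525 ± 85 from 3.88 ± 1.5 CPM, and the chemokine Cxcl16 to 306 ± 21 from 24.4 ± 2.8 CPM. Csf3 rose to 13.9 ± 1.4 from 0.129 ± 0.022 CPM. Besides Cxcl12, complement C3 fell from 777 ± 170 to 4.37 ± 1.0 CPM.

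**Figure D3:**
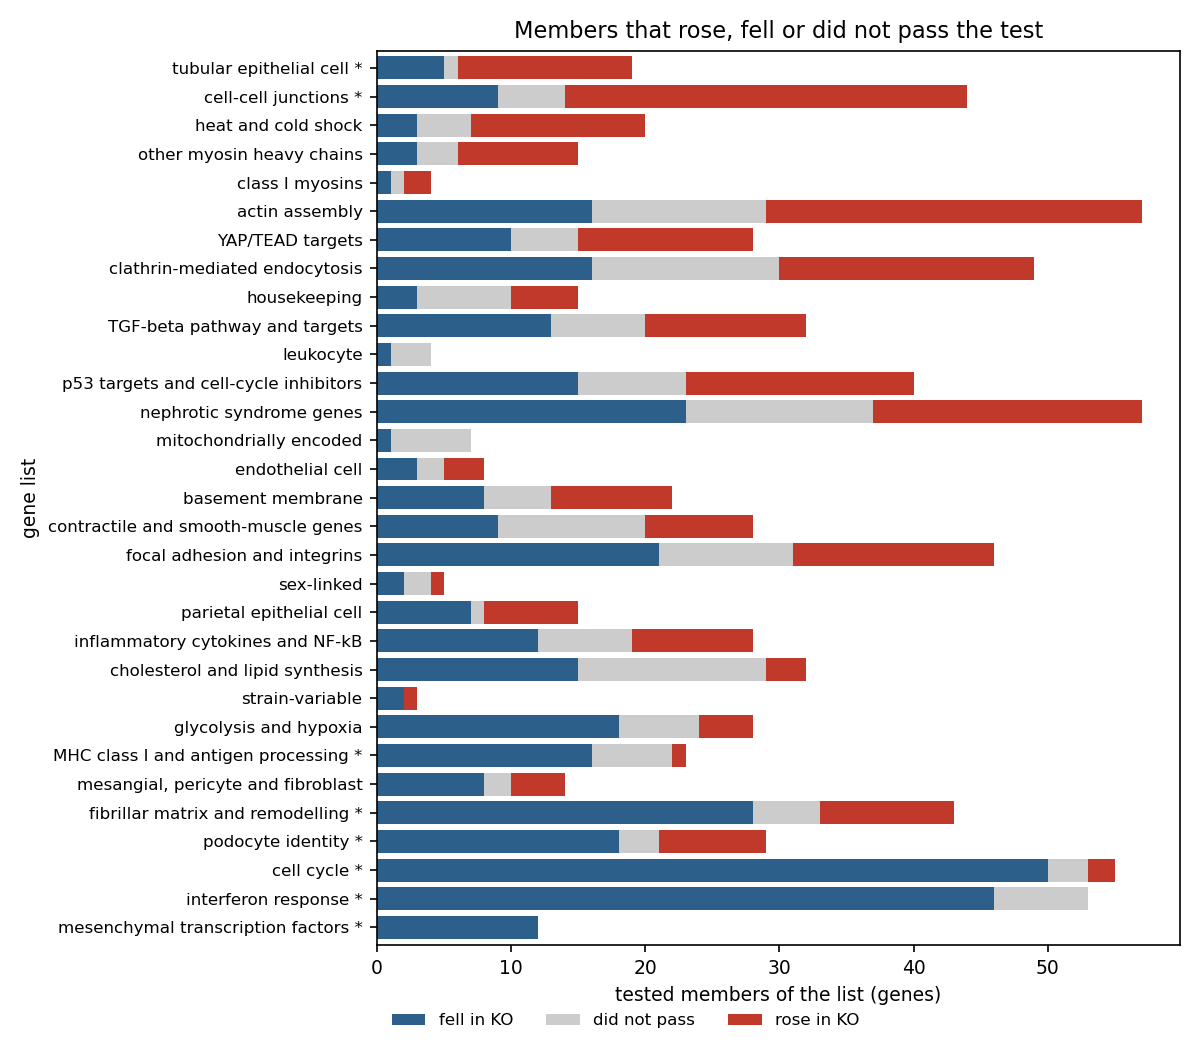
Number of tested members of each of the 31 gene lists that fell (blue), did not pass (grey) or rose (red) in the KO line, ordered by the median log2 fold change of the list. Asterisks mark the 8 lists past the threshold of the camera test with its preset correlation, among them cell cycle with 50 of 55 members lower and cell-cell junctions with 30 of 44 higher.

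Targets of growth-factor and mechanical signalling were divided. Of 28 YAP/TEAD targets 13 rose and 10 fell (camera adjusted p = 0.676). Ccn2, a matricellular protein, rose to 3594 ± 300 from 431 ± 128 CPM and Igfbp3 to 17.5 ± 3.7 from 0.703 ± 0.17 CPM, while the receptor kinase Axl fell from 860 ± 149 to 253 ± 33 CPM. Of 32 genes of the TGF-beta pathway 12 rose and 13 fell (camera adjusted p = 0.978, median log2 fold change 0.06 and mean -0.11). Pmepa1, a TGF-beta-induced inhibitor of the pathway, rose to 524 ± 71 from 30.4 ± 11 CPM and the ligand Tgfb3 to 32.7 ± 7.3 from 2.48 ± 0.28 CPM. The BMP target Id3 fell from 267 ± 69 to 21.3 ± 10 CPM, the co-receptor Tgfbr3 from 159 ± 17 to 11.2 ± 1.7 CPM and Bmper from 38.2 ± 10 to 0.388 ± 0.2 CPM.

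Markers of other kidney cell types were also measured. Of 30 mesangial, pericyte and fibroblast markers 14 were tested, of which 4 rose and 8 fell, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.178). The call changed with a stricter filter on low values (adjusted p = 0.0171, with 0.0171 to 0.333 over 16 other camera fits with the preset correlation; adjusted p = 0.825 with an estimated correlation). Pdgfrb, the receptor of mural cells, fell from 114 ± 24 to 0.192 ± 0.071 CPM, and Fbln2 rose to 1326 ± 328 from 353 ± 157 CPM. Of 23 endothelial markers 8 were tested, of which 3 rose and 3 fell (camera adjusted p = 0.978, median log2 fold change -0.08 and mean 0.44). The receptor Flt4 rose to 164 ± 29 from 4.41 ± 0.64 CPM, and Plat fell from 748 ± 85 to 178 ± 23 CPM. Of 25 leukocyte markers 4 were tested, and the monocyte co-receptor Cd14 fell from 22.5 ± 4.9 to 13.3 ± 1.2 CPM as the 1 member that passed (camera adjusted p = 0.978, median log2 fold change 0.05 and mean -0.05).

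The counts of members were those adjusted over all genes tested, and 26 of the 31 lists had the same counts adjusted over the list alone. With the preset correlation 8 lists passed, 2 higher and 6 lower in the KO line. With an estimated correlation 0 passed, and 4 had an unadjusted p under 0.05, while the self-contained fry test called 20.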

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

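All alternatives here were chosen before the data were examined. Genes past the threshold numbered 7565 to 9973 in 10 alternatives of scaling, filter, variance model and weights, and 7573 to 8323 with one library left out. In all 16 of these fits, 7554 to 8587 of the 8590 called genes were called in the same direction, and 0 were called in the opposite one. The upper value of 9973 came from sample weights, whose estimation did not converge and gave WT replicate 2 a weight of 8.55. The lowest came from the stricter filter, which tests 11171 genes. voom on the recovered reads called 8599 genes, 8555 of them shared. Genes past the threshold and 2-fold numbered 2504 to 3662, and 3473 to 3559 with one library left out. The lowest of these was limma treat, which asks for a change beyond 2-fold and called 1056 higher and 1448 lower genes. The Myo1e log2 fold change stayed between -3.42 and -3.28. Other scalings moved the median of all genes by at most 0.048 on the log2 scale.

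Gene lists past the threshold were 8 in the camera test with its preset correlation, 8 to 10 in its 16 other fits, 0 with an estimated correlation (4 at an unadjusted p under 0.05, lowest adjusted p = 0.338) and 20 with fry. With an estimated correlation, camera also refers its statistic to the few degrees of freedom that 6 libraries leave. With the preset correlation it uses those of all genes tested. The loss of calls is thus not by itself evidence of correlated genes. How much of it each of these parts caused was not tested, but a higher correlation is argued against for the tubular epithelium and podocyte identity lists. Their estimated correlations were -0.049 and 0.0076, under the preset of 0.01. Their unadjusted camera p still rose from 0.00023 to 0.016 and from 0.0040 to 0.042. The remaining lists of the 8 had estimates above the preset, from 0.056 for cell-cell junctions to 0.51 for the cell cycle. The class I myosins, which camera placed on the higher side without passing, passed fry on the lower side, with a median log2 fold change of 0.26 in both (adjusted p = 0.00314). The cause of that was not tested, and the mean was -0.36. Of 558 values for single lists, 532 kept their direction and side of the threshold, 8 no longer passed, all with the estimated correlation, and 17 newly passed. Of 2739 values for 172 named genes, 2721 kept both, and 18 no longer passed, in 8 genes of small or variable change (Dnajb1, Egfl7, Eif2s3x, Glo1, Pgk1, Sfrp2, Synj1 and Tjp1).

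With the replicate block, 8395 genes passed, 3520 of them 2-fold, the Myo1e log2 fold change was -3.35 and 8 lists passed. Deviations from the group mean correlated at 0.1, 0.08 and -0.10 for the same-numbered libraries 1, 2 and 3. These low values gave no sign of pairing. They cannot exclude it, because the 3 deviations of a group add up to 0 and the labels do not say how the cultures were kept apart.

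Depth limits the lowest genes. In a library 3 reads equal 0.0703 to 0.0856 CPM, so lower levels rest on fewer reads than that per library, and 71 to 138 genes per library had 0 reads.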

Other observations

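The tests on mixed cells, on a mislabelled sample, on the lines per genotype, on the remaining Myo1e reads, on shifts along chromosomes and on X-linked genes were chosen only after the results were seen.

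Metabolic genes differed between the lines in part. Of 28 genes of glycolysis and hypoxia 4 rose and 18 fell in the KO line, with a median log2 fold change of -0.50 (camera adjusted p = 0.0679). The list passed with quantile normalization (adjusted p = 0.046), with the stricter filter (adjusted p = 0.0493) and without WT replicate 3 (adjusted p = 0.0368), with 0.0368 to 0.105 over 16 other camera fits with the preset correlation, and had an adjusted p = 0.843 with an estimated correlation. The stress-induced gene Ndrg1 fell from 1073 ± 57 to 219 ± 53 CPM and the neuronal enolase Eno2 from 22.8 ± 3.8 to 2.86 ± 0.8 CPM, while the hexokinase Hk2 rose to 181 ± 24 from 35.3 ± 18 CPM and Pfkfb3 to 93.0 ± 11 from 41.3 ± 9.5 CPM. Of 32 genes of cholesterol and lipid synthesis 3 rose and 15 fell, or 3 and 14 adjusted over the list alone (camera adjusted p = 0.112, and 0.0154 without WT replicate 1, with 0.0154 to 0.452 over 16 other camera fits with the preset correlation; adjusted p = 0.966 with an estimated correlation). The desaturases Fads1 and Scd1 fell from 552 ± 24 to 156 ± 14 CPM and from 90.9 ± 15 to 24.4 ± 4.6 CPM. Of 20 heat and cold shock genes 13 rose and 3 fell (camera adjusted p = 0.0898), with the small heat shock protein Hspb1 at 157 ± 24 against 38.5 ± 2.4 CPM and Hspb8 at 2.06 ± 0.48 against 44.4 ± 3.9 CPM. Hspa1a and Hspa1b rose too, but are near-identical copies that could share reads.

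Genes used as references were not all level. Of 15 housekeeping genes 5 rose and 3 fell (camera adjusted p = 0.794). Gusb and Hprt rose to 112 ± 6.6 from 59.1 ± 2.9 CPM and to 158 ± 16 from 87.5 ± 3.9 CPM. Of 13 mitochondrially encoded genes 7 were tested and 1 passed, mt-Nd6, lower at 5.70 ± 2.3 against 15.3 ± 3.4 CPM (camera adjusted p = 0.978). It lies on the strand opposite to most other mitochondrial genes. Xist, transcribed from the inactive X chromosome of female cells, was at 696 ± 95 in the KO line and 1182 ± 196 CPM in the WT line. Of 10 sex-linked genes 5 were tested, of which 1 rose and 2 fell (camera adjusted p = 0.613), and the Y-linked genes of the list were not among the genes tested. Of 11 genes that vary between mouse strains 3 were tested, of which 1 rose and 2 fell (camera adjusted p = 0.559), with Wdfy1 at 15.2 ± 0.98 against 107 ± 11 CPM.

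Keratins and claudins were abundant in the KO line and near 0 in the WT line, while vimentin went the other way. Other cells rich in keratins and claudins, mixed into cultures of cells with the transcripts of the WT line, would leave the abundant transcripts of that line at the share of its cells. Of 6505 genes with at least 32 CPM in the WT line, 68 had a KO level whose upper 95% limit was under 1% of the WT level, among them Vim at 0.16%, Inmt at 0.0776% and Nid1 at 0.0982%, which argues against a mixture in which such cells made up 1% or more. A mislabelled sample was also tested, and the lowest correlation within a group exceeded the highest between groups by 0.275, so no library resembled the other group. Loss of Myo1e and the difference between lines cannot be told apart, since the labels name 1 line per genotype, and the difference of epithelial and mesenchymal genes may belong to either.

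Of the WT level of Myo1e, 9.79% remained in the KO libraries. Reads or cells of the WT line in the KO libraries are argued against, because 67 genes with at least 32 CPM in the WT line had an upper limit under 0.979%, far below the Myo1e percentage. A transcript made from the disrupted gene is a candidate explanation and stays open. The table gives 1 value per gene, with 0 genes listed more than once, so reads could not be placed on exons.

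Log2 fold changes differed between chromosomes. Relative to the median of all 12466 placed genes, the median was 0.41 higher on chromosome 11 (1028 genes, 71.8% above that median), 0.37 lower on chromosome 15 and 0.42 lower on chromosome 19, each with a permutation p = 0.0001, the smallest that 10000 draws give (adjusted p = 0.000182). Among 8915 genes with at least 3 log2 CPM in both lines, the shifts were 0.38, -0.40 and -0.37. A difference in chromosome copy number between the lines is a hypothesis that these values could bear out, as 3 chromosomes moved by at least 0.2. All 3 parts along their length shifted the same way, which adds little, since a chromosome chosen for a shifted median favours parts of 1 sign. Which line departs from a normal set was not tested. Regional shifts within chromosomes stay open, since the parts differed in sign in 0 of the 16 chromosomes past the threshold, but chromosomes chosen for a shifted median favour parts of 1 sign, and for shifts that vary along chromosomes 0 of all 20 passed a permutation of gene order (1 at an unadjusted p under 0.05).

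Among genes under 0.1 CPM in the KO line and with at least 4 CPM in the WT line, 7 of 95 were X-linked (7.37%), Prdx4 and Zfp275 included, against 2.94% of all 10626 placed genes at that WT level (Fisher's exact two-sided p = 0.0215). In the opposite direction 3 of 124 genes were X-linked (Fisher's exact two-sided p = 1). That more genes are switched off on the X than on autosomes in the KO line is a hypothesis found in the same data, and may rest on few genes.

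The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 8590 genes past the threshold and 3517 past the threshold and 2-fold. The highest of the others called 0 in both counts (limma, with 2 to 200 genes at an unadjusted p under 0.05), so that 1 of the 10 splits gave as many. Every other split put libraries of both lines into each group, so the difference between the lines entered the spread within groups. Few calls were thus set in advance there, and the gene counts cannot test whether chance gave the result. For gene lists the real split called 8, the highest of the others 11, and 3 of the 10 splits gave as many. The groups of every other split held unequal numbers of KO libraries, so part of the difference between the lines stayed between them. camera compares genes with each other and can still call lists from that part. The list counts therefore cannot test whether chance gave the result either.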
